A study of Homo sapiens with 158 samples.

How the data were processed

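RNA from formalin-fixed, paraffin-embedded pancreatic ductal adenocarcinoma tissue of 79 patients was measured on 2 platforms, which gave 158 libraries. Per the labels' protocols, total RNA was extracted from the fixed tissue. One library per patient was made after ribosomal RNA depletion (KAPA RNA HyperPrep with RiboErase) and sequenced as a whole transcriptome. The other came from a commercial exome capture assay (Tempus), in which probes against coding exons enrich the library before sequencing. Platform and patient were taken from the labels, and the patient number pairs the 2 libraries. Whether both libraries came from one RNA extraction is not given in the sources used here.

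The submitters' processing notes name bcl2fastq, Salmon 1.5.2, kallisto 0.44.0 and the builds GRCh38.p13 and GRCh37, with no statement of which tool or build made which table. The authors deposited one table per platform, with gene symbols in rows. The whole-transcriptome table held deposited TPM values for 24416 symbols. Its library totals ran from 568735 to 963809, with a median of 872590. TPM keeps no sequencing depth, so depth is unknown for those libraries and no counting interval was given.

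The deposited exome capture table, of 17689 symbols, was found from its values to hold the natural log of a normalized expression value plus 1. In 2309 genes the lowest values, under 0.02, followed one factor per gene and one per library. After back-transformation as a natural log, 45.1% of the next values lay within 0.05 of a whole multiple of 1000 times that floor, and 38.4% lay within 0.001. Read as log2 the shares were 7.36% and 0.18%, and read as log10 they were 9.32% and 0.19%. The inverse of the library factor of the floor ranged from 0.52 to 2.26 of its median, a relative depth under the assumption that the floor is one constant number of reads. The design had been written for TPM in both tables. The natural log values were therefore back-transformed with exp(value) − 1 before any comparison of levels. How the authors normalized them before the log is not given in the sources used here.

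Some exome capture values were too large for one log value. The natural log of 1000000 is 13.8, while the table reached 67.7. Genes with any value above 15 (351 genes) or a median more than 3 natural log units (20.1-fold) above a lowess trend on the whole-transcriptome level (794 genes) were left out of level comparisons. Together these were 810 of the 17463 genes shared by both tables, called oversized below. Only those over the ceiling are too large for one log value. They stayed in rank correlations, where each gene is compared only with itself. Y-linked genes, XIST and TSIX (98 symbols) were removed at the start. No 2 libraries held identical values, and each column of sample values was used. For 3 patients the whole-transcriptome table listed over 20% of the shared genes at 0, against a median of 10.1%. The pair orders and their number, the calls, the score, the gene and list level tests and the median rho were repeated on the other 76 patients. The log ratios, the rho of the lists, the detected genes and the class shares were not.

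Each library of both tables was rescaled to a total of 1000000 over the remaining 16653 genes and the values were converted to log2(value + 1). These genes held a median of 30.4% of the whole-transcriptome TPM. Fold changes on this scale understate the change of low genes. The tables had been normalized separately, so a level difference between platforms includes the chemistry, the quantification and this rescaling. The pair orders, log ratios and ranks were computed within a library or within a table. Genes with a median of at least 1 on this scale on at least 1 platform (13765 genes) were tested with limma 3.58.1 in R 4.3.3 on the within-patient differences, exome capture minus whole transcriptome, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The lists, the comparisons and the rule for named genes were fixed before the data were examined. Of the 35 lists, 29 could be tested. The lists of immunoglobulin and T cell receptor genes, replication-dependent histones, mitochondrially encoded genes, long noncoding RNA and small structured RNA had no shared members, and the list of HLA and antigen presentation genes kept too few for a level test. The subtype lists (PurIST pairs, Moffitt, Collisson) were written from knowledge of the published lists and were not checked against them.

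For each of the 8 PurIST pairs, a library was basal-ordered if the basal-like gene exceeded the classical one. Orders were compared by the exact two-sided McNemar test with Clopper-Pearson 95% intervals, and log ratios by a two-sided permutation test with 100000 swaps of platform within patients. A library was called basal-like at 5 or more basal-ordered pairs, since the published weights are not given in the sources used here. Cohen's kappa had a bootstrap interval from 10000 draws. Spearman's rho between platforms was computed per gene over the patients, on the rescaled values or, for oversized exome capture values, on the deposited ones. Genes needed a median of at least 1 on either platform, or on the whole transcriptome where the exome capture values were oversized. List medians were placed among 10000 random lists matched on whole-transcriptome expression. Analyses outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and scikit-learn 1.9.0.

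The patient numbers pair libraries of the same person by their labels. Deviations from the platform mean, over 13764 genes, correlated with a median of 0.525 within patients and −0.019 between patients, and 77 of 79 pairs exceeded 0.1. On simulated within-patient differences for the 13765 genes, with 200 genes shifted by known amounts, limma recovered 100% at each of the 4 sizes with 0 false calls. Each gene had first been centred on 0, and the shifts of 1.3 and 2 either way lay beyond the threshold of 1. This checks the procedure and not the scale of the tables. Simulated gene pairs with true correlations of 0.3, 0.6 and 0.9 gave median rho of 0.289, 0.581 and 0.888.

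Named genes were the 16 pair genes, the 10 largest called differences each way with one direction in at least 90% of patients, up to 4 members per list (largest called rise and fall, lowest and highest rho), and the 5 lowest and 5 highest rho among list genes. This gave 134 genes, of which those named in the text are a part. The values of 1 pair and of some named genes are not reported here, although counts and summaries include them. Alternatives covered the pairing, the pseudocount, the filter, the scaling, ties, call thresholds, the correlation measure and detection thresholds. Gene neighbours were taken from the RefSeq annotation of GRCh38.p14, used for names and order only. No check of transcript length or GC content was made, because no transcript set of the builds used was at hand.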

Results

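The data set held paired expression profiles of 79 pancreatic ductal adenocarcinomas. Each tumour had 1 ribosomal RNA-depleted whole-transcriptome library and 1 exome capture library. The series compares expression-based molecular subtyping between the 2 platforms, so the comparisons ran within patients. They covered the gene pairs of a published subtype classifier, the calls made from them, the level of each gene, and the order of the tumours for each gene. The tables were made separately and were put on one scale here, so level differences include quantification.

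The first comparison asked whether the gene pairs of the PurIST classifier, which sets a basal-like gene against a classical gene in one library, had the same order on both platforms. BCAR3, an adaptor of integrin signalling, exceeded GATA6, an endodermal transcription factor, in 6 of 79 patients on the whole transcriptome and in 59 on exome capture. The order matched in 32.9% of patients (95% Clopper-Pearson interval 22.8% to 44.4%). ITGA3, an integrin subunit, exceeded the intestinal lectin LGALS4 in 19 patients on the whole transcriptome and in 65 on exome capture, with 41.8% matching (30.8% to 53.4%). KRT6A, a keratin of stratified epithelium, exceeded ANXA10 in 24 and 52 patients, with 64.6% matching (53.0% to 75%). Every discordant patient in these 3 pairs was basal-ordered on exome capture alone (exact McNemar test, adjusted p = 1.8e-15, 1.1e-13 and 2e-08).

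**Figure D1:**
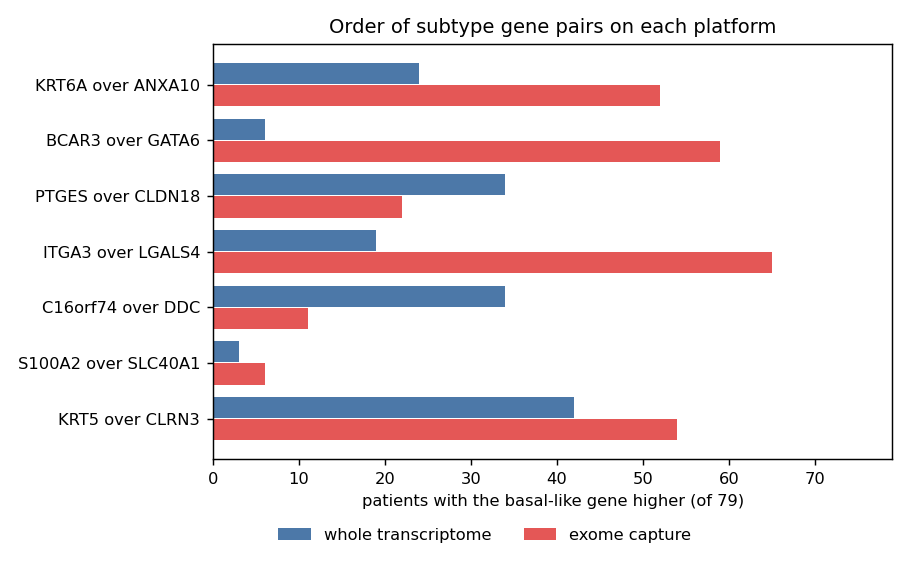
Number of the 79 patients (x axis) in whom the basal-like gene exceeded the classical gene of 7 pairs (y axis), with one bar per platform. BCAR3 over GATA6 went from 6 patients on the whole transcriptome to 59 on exome capture, while C16orf74 over DDC went from 34 to 11.

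The other pairs moved less, and a pair of them moved the opposite way. KRT5 exceeded CLRN3 in 42 patients on the whole transcriptome and 54 on exome capture, with 74.7% matching (adjusted p = 0.014, 16 patients changing to basal-ordered against 4 changing back). C16orf74 exceeded DDC, the aromatic amino acid decarboxylase, in 34 patients on the whole transcriptome and 11 on exome capture, with 70.9% matching (adjusted p = 4.8e-07, 0 against 23). PTGES, a prostaglandin E synthase, exceeded the gastric claudin CLDN18 in 34 and 22 patients, with 77.2% matching (adjusted p = 0.01, 3 against 15). S100A2 over SLC40A1, the iron exporter ferroportin, matched in 96.2% of patients and did not pass the test (adjusted p = 0.25). The tests for PTGES and CLDN18 and for KRT5 and CLRN3 no longer passed once orders within 1.5-fold were left out (unadjusted p = 0.07 and 0.11).

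The log2 ratios of these pairs showed the same directions. BCAR3 to GATA6 was −1.33 ± 1.09 (SD, n = 79) on the whole transcriptome and 0.78 ± 1.17 on exome capture, a difference of 2.11 that was positive in 79 of 79 patients. KRT6A to ANXA10 rose by 3.14, from −1.24 ± 3.36 to 1.90 ± 3.59, in 75 patients. ITGA3 to LGALS4 rose by 2.20 in 78 patients. PTGES to CLDN18 fell by 1.07 in 63 patients, and C16orf74 to DDC fell by 1.19 in 61 (two-sided permutation tests, adjusted p = 1.1e-05 each, from the smallest p that 100000 swaps can give). S100A2 to SLC40A1 rose by 0.56 in 58 patients (adjusted p = 0.00012). Without the pairing of patients that ratio did not pass the test (unadjusted p = 0.11).

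Tumours had on average 2.17 ± 1.97 (SD, n = 79) basal-ordered pairs of 8 on the whole transcriptome and 3.67 ± 1.96 on exome capture. The number was higher on exome capture in 60 patients, equal in 17 and lower in 2, with a mean difference of 1.51 ± 0.145 (SE, permutation p = 1e-05, the smallest that 100000 swaps can give). With 5 or more pairs as the threshold, 10 tumours were called basal-like on the whole transcriptome and 27 on exome capture. The same call was made for 62 of 79 patients, 78.5% (67.8% to 86.9%), with Cohen's kappa of 0.436 (bootstrap 95% interval 0.242 to 0.635). The 10 tumours basal-like on the whole transcriptome were basal-like on exome capture too, and the 17 calls that differed were basal-like on exome capture alone (exact McNemar p = 1.5e-05). With the mean platform difference of each pair removed, 6 calls differed and 92.4% matched (kappa 0.727, p = 0.031).

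**Figure D2:**
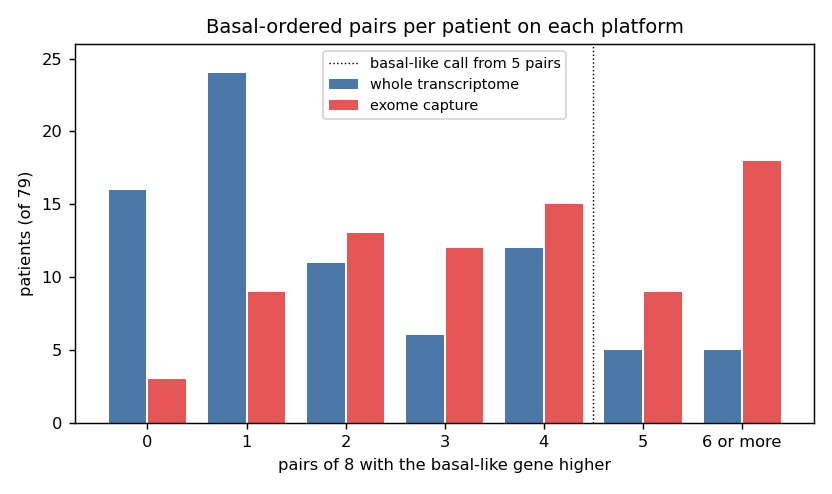
Number of patients (y axis, of 79) by how many of the 8 pairs had the basal-like gene higher (x axis), for each platform, with the threshold for a basal-like call dotted. On the whole transcriptome 16 patients had 0 such pairs and 5 had 6 or more, against 3 and 18 on exome capture.

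A score over longer lists, the mean log2 level of 24 Moffitt basal-like genes minus that of 22 Moffitt classical genes, was −1.63 ± 1.624 (SD, n = 79) on the whole transcriptome and −0.78 ± 1.53 on exome capture. The score was higher on exome capture in 68 patients, by 0.84 ± 0.121 (SE, permutation p = 1e-05). This difference depended on the scale. With the same genes on the deposited scales, exome capture values converted to log2, the difference was 0.04 ± 0.147 (SE, p = 0.81), and with CTSE and CEACAM6 added it was −0.80 ± 0.151 (p = 1e-05). The scores of the 2 platforms correlated over patients with Pearson's r = 0.768 and Spearman's rho = 0.741 (permutation p = 1e-05 each). Pearson's r was 0.713 without the 2 patients farthest from the median. By the Bayesian information criterion 1 cluster described the scores on each platform, and the labels give no batches within a platform. The classical genes CTSE and CEACAM6 were left out of the main score because their exome capture values were oversized, over a ceiling or far above the trend.

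Across 13765 genes, 1966 were higher and 3382 lower on exome capture (limma, adjusted p under 0.05 and an absolute log2 difference of at least 1). Of these 5348 genes, 4972 went the same way in at least 90% of patients. The median gene differed by −0.25 on the log2 scale, and the other differences should be read relative to it. With libraries centred on their median, 3049 genes were higher and 2112 lower, and with quantile normalization 2500 and 2461. The excess of lower genes also depended on leaving out genes far above the trend on exome capture, a limit with no counterpart for low genes. With all of these kept, 2770 genes were higher and 3383 lower, and with those over the ceiling alone left out, 2424 and 3382. The genes furthest below their whole-transcriptome level included ribosomal protein genes, with RPL21 at −7.29 ± 0.15 (SE, lower in 78 of 79 patients), RPS26 at −6.45 ± 0.1, RPS28 at −5.37 ± 0.2 and RPL41 at −5.24 ± 0.1. Processed copies of ribosomal protein genes can share their reads, so these values are uncertain. HBB, the beta chain of haemoglobin, fell by 5.17 ± 0.2 in 77 patients. SMIM3 (−6.18 ± 0.12), PIGY (−6.11 ± 0.066), MIA2 (−5 ± 0.074), SRSF8 (−4.99 ± 0.08) and SNURF (−4.76 ± 0.14) completed the 10 largest falls, and all 10 had a limma adjusted p of 4.8e-41 or less. On exome capture SMIM3, SNURF, SRSF8 and PIGY had mean log2(value + 1) of 0.0027, 0.014, 0.16 and 0.46, near the floor. The size of these falls is therefore mostly their whole-transcriptome level, and the cause was not tested.

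Among the genes kept, the largest rises included SIK1, a salt-inducible kinase, at 4.36 ± 0.28 (SE, higher in 79 of 79 patients) and SRCAP, a chromatin remodeller, at 3.85 ± 0.057. The SD of SIK1 was 2.457 on the whole transcriptome and 0.966 on exome capture, and its Spearman's rho between platforms was 0.0501. The platforms thus did not order the tumours alike for SIK1, and the size of its rise is uncertain. ZFHX3, a large homeobox transcription factor, rose by 3.79 ± 0.075 in 78 patients, and SULT1A3 by 3.68 ± 0.19 in 78. SULT1A3 has a near-identical copy, so its value is uncertain. Genes more than 20.1-fold above the trend on exome capture were left out, so larger rises are not ranked here, while falls had no such limit. GPR173 (3.86), PCDHB5 (3.84), BEX5 (3.72), C17orf58 (3.68) and FKBPL (3.66) also rose, and these 5 sit beside a gene with oversized exome capture values. Such neighbours were found for 7.58% of the genes higher on exome capture, 2.69% of those lower and 3.36% of those not called.

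Among the 16 pair genes, 3 rose and 3 fell, the same counts when adjusted over the list alone. KRT6A was higher on exome capture by 2.49 ± 0.15 (SE), BCAR3 by 1.68 ± 0.063 and ITGA3 by 1.47 ± 0.086. KRT6A has close paralogs that can share its reads, so its value is uncertain. C16orf74 fell by 1.82 ± 0.095, and REG4 (−1.56 ± 0.21) and PTGES (−1.31 ± 0.11) fell too. The call for PTGES was lost with median centring (−0.94) and with quantile normalization (−0.90). SLC40A1 differed by −0.97 ± 0.094 and gained a call with quantile normalization (−1.11) and without the 3 patients with many genes at 0 in the whole-transcriptome library (−1.05). GATA6 differed by −0.42 ± 0.069 and LGALS4 by −0.74 ± 0.13, below the threshold of 1. KRT5 differed by 0.80 ± 0.13 and passed it with median centring (1.17), quantile normalization (1.1) and a pseudocount of 0.1 (1.05).

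Of the 22 Moffitt classical genes tested, 9 fell and 3 rose on exome capture (12 adjusted over the list alone). LYZ, lysozyme, fell by 2.46 ± 0.15 (SE) and the trefoil factor TFF1 also fell (−2.45 ± 0.18), while the brush border myosin MYO1A rose by 1.86 ± 0.18. Of the 22 Moffitt basal-like genes, 4 rose and 2 fell (6 adjusted over the list alone). FAM83A rose by 2.55 ± 0.13 and TNS4 by 2.14 ± 0.11, and LY6D fell by 1.32 ± 0.12, a call lost with median centring (−0.96). Neither list passed camera (adjusted p = 0.56 and 0.42), and for the basal-like list the median of −0.21 had the opposite sign to the mean of 0.17 and turned to 0.15 with median centring and 0.69 with a minimum median of 5. The Collisson classical list had 2 rises and 7 falls in 20 genes, with ERBB3 at 2.08 ± 0.084. The Collisson quasimesenchymal list had 2 rises and 9 falls in 18, with CKS2 at −2.71 ± 0.11 (camera adjusted p = 0.86 and 0.38).

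Camera at the preset correlation passed 6 of 29 lists, and none held with an estimated correlation. The activated stroma list was higher on exome capture, with 16 rises and 2 falls in 30 genes (18 adjusted over the list alone) and a median of 1.45 (adjusted p = 7.9e-05, and adjusted p = 0.999 with an estimated correlation). Its median was 1.81 with median centring and 0.955 with quantile normalization. ITGA11, a collagen-binding integrin subunit of fibroblasts, rose by 3.45 ± 0.1 (SE) and the fibrillar collagen COL11A1 by 3.33 ± 0.13, while GREM1, a BMP antagonist, fell by 1.95 ± 0.13. All 21 acinar genes tested fell (21 adjusted over the list alone), with a median of −3.09 (adjusted p = 0.023, and adjusted p = 0.999 with an estimated correlation). Another 5 of the 26 acinar genes were left out as oversized, a limit that can remove only high exome capture values. With oversized genes kept, the median was −2.68 and the list did not pass camera (adjusted p = 0.071). SPINK1, the pancreatic trypsin inhibitor, fell by 4.66 ± 0.23 and REG1B by 2.48 ± 0.27. The acinar list did not pass without the pairing of patients (adjusted p = 0.44) or without the 3 patients with many genes at 0 in the whole-transcriptome library (adjusted p = 0.075).

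Of 49 ribosomal protein genes, 29 fell and 1 rose (30 adjusted over the list alone), with a median of −1.33 (adjusted p = 0.0026, and adjusted p = 0.999 with an estimated correlation). RPL14 was the gene that rose, by 2.44 ± 0.055 (SE). Of 16 S100 genes, 14 fell and 0 rose (14 adjusted over the list alone), with a median of −1.66 (adjusted p = 0.0031, and adjusted p = 0.999 with an estimated correlation). S100A8, a calcium-binding protein of neutrophils, fell by 3.01 ± 0.16, while S100A2 differed by −0.42 ± 0.1. Of 27 nuclear oxidative phosphorylation genes, 15 fell and 0 rose (15 adjusted over the list alone), with a median of −1.19 (adjusted p = 0.025, and adjusted p = 0.999 with an estimated correlation). NDUFB1, a subunit of complex I, fell by 4.15 ± 0.13, and NDUFV1 differed by 0.13 ± 0.064, or by −0.06 with quantile normalization. Of 15 keratins, 4 rose and 0 fell (4 adjusted over the list alone), with a median of 0.64 (adjusted p = 0.046, and adjusted p = 0.999 with an estimated correlation). The keratin list did not pass without the pairing (adjusted p = 0.3) or with either other scaling (adjusted p = 0.091 and 0.15), or without the 3 patients (adjusted p = 0.057). With the oversized genes kept, the activated stroma and S100 lists alone passed.

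**Figure D3:**
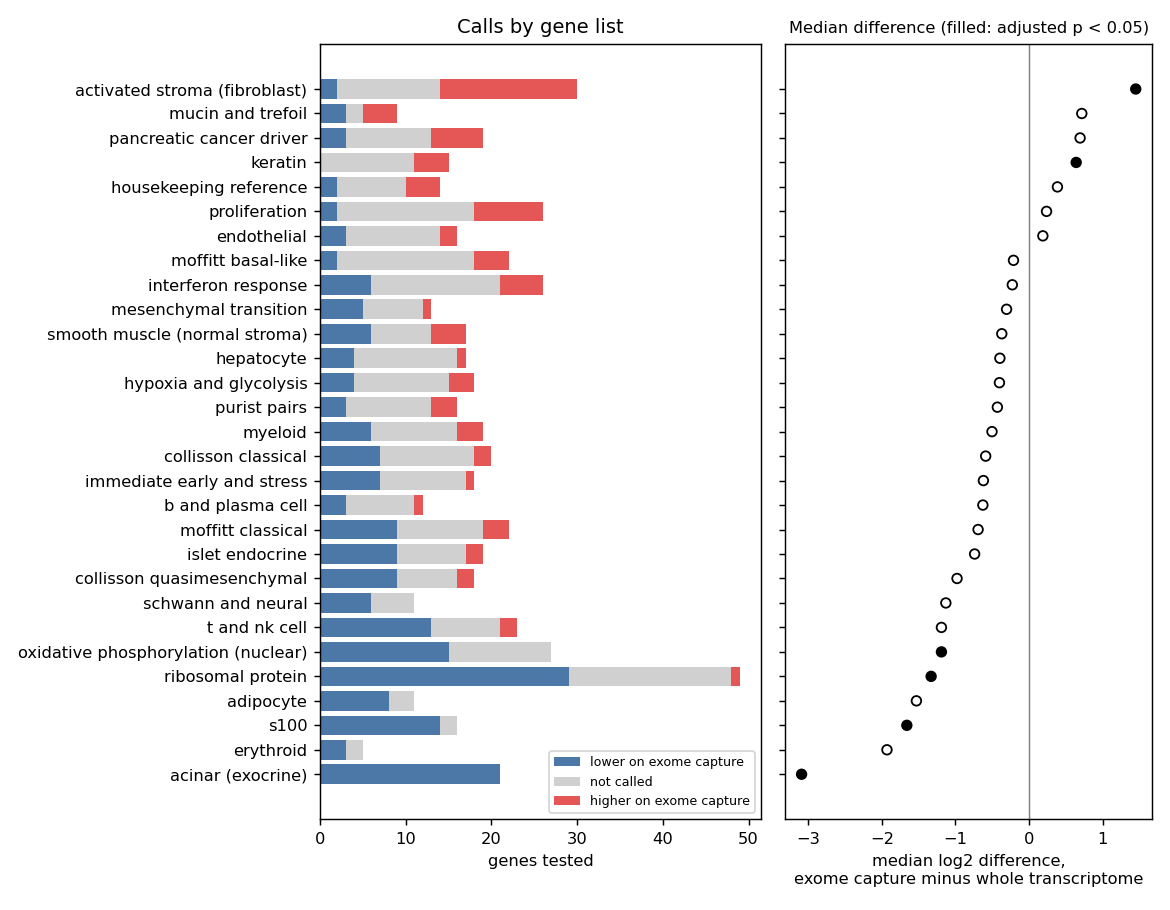
Left, number of tested genes per fixed list that were lower, not called or higher on exome capture; right, the median log2 difference of each list, exome capture minus whole transcriptome, filled where camera at the preset correlation gave an adjusted p under 0.05. Activated stroma lies highest at 1.45 and acinar genes lowest at −3.09.

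The other lists did not pass camera in the main test. The calls within them were the same in number when adjusted over the list alone, as in all 29 lists. Adjusted p was under 0.05 in 12297 of 13765 genes, so the log2 threshold decided most calls and this adjustment could change little. In the proliferation list 8 of 26 genes rose and 2 fell (median 0.24, adjusted p = 0.066, and median 0.64, adjusted p = 0.011 with quantile normalization), with the division marker MKI67 at 2.90 ± 0.1 (SE) and the kinase CDK1 at −1.27 ± 0.11, which lost its call with median centring (−0.91) and quantile normalization (−0.90). Of 19 pancreatic cancer driver genes 6 rose and 3 fell, with ARID1A, a chromatin remodeller subunit, at 2.89 ± 0.059. T and NK cell genes had 2 rises and 13 falls in 23, with LCK at 1.2 ± 0.13 and KLRD1 at −2.27 ± 0.093. Adipocyte genes had 0 rises and 8 falls in 11, led by FABP4 at −3.11 ± 0.19. Endothelial genes had 2 rises and 3 falls in 16, with von Willebrand factor VWF at 2.83 ± 0.093. Smooth muscle genes had 4 rises and 6 falls in 17, with MYH11 at 2.52 ± 0.14 and ID4 at −3.14 ± 0.089. Islet genes had 2 rises and 9 falls in 19, with insulin (INS) at −3.30 ± 0.28.

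Of the remaining lists, myeloid genes had 3 rises and 6 falls in 19 (CSF1R at 1.66 ± 0.066, TYROBP at −3.01 ± 0.12, SE). B and plasma cell genes had 1 rise and 3 falls in 12, interferon response genes 5 and 6 in 26 (median −0.23, with camera in the upward direction), and hypoxia and glycolysis genes 3 and 4 in 18. Immediate early and stress genes had 1 rise and 7 falls in 18, with IER2 at −2.82 ± 0.073 and MYC at 1.47 ± 0.097. Mesenchymal transition genes had 1 rise and 5 falls in 13, with E-cadherin (CDH1) at 1.43 ± 0.076 and TWIST2 at −2.41 ± 0.092. Hepatocyte genes had 1 rise and 4 falls in 17 (median −0.40, with camera in the upward direction), Schwann and neural genes 0 and 6 in 11, erythroid genes 0 and 3 in 5, and mucin and trefoil genes 4 and 3 in 9 (median 0.72, adjusted p = 0.39). The last list had 6 of its 15 genes left out as oversized. Its median was 2.71 with the ceiling rule alone (adjusted p = 0.044) and 2.74 with all kept (adjusted p = 0.053). Reference genes commonly used for normalization had 4 rises and 2 falls in 14, with POLR2A, which sits beside an oversized gene, at 3.62 ± 0.066, HPRT1 at −2.60 ± 0.072 and GAPDH at −0.63 ± 0.074. Among HLA and antigen presentation genes, too few for the list test, B2M fell by 2.32 ± 0.12 and the transactivator CIITA rose by 2.23 ± 0.076.

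The next comparison asked whether tumours kept their order for a given gene. Over 14381 genes the median Spearman's rho between platforms was 0.385 ± 0.033 (jackknife SE over 79 patients), with quartiles of 0.24 and 0.523. In 100 shuffles of the patient pairing the highest median was 0.0669. Acinar genes had a median rho of 0.773, and islet genes 0.763. The hormone gene PPY reached 0.888 (r = 0.895, and 0.882 without the 2 patients farthest from the median). TNS4 reached 0.841 (r = 0.853), KRT6A 0.838 (r = 0.874), MUC16 0.838 (r = 0.834) and APOH 0.825 (r = 0.863), with r of 0.831, 0.846, 0.819 and 0.802 without those patients. Each of these had an adjusted permutation p of 1.8e-05 for rho and 1.9e-05 for r over the 134 named genes, from the smallest p that 100000 permutations can give. These genes were named because their rho was the highest among list genes, so the p-values are no independent support. MUC16 was oversized on exome capture, and its rho and r used the deposited values. Among the pair genes rho ran from 0.409 for SLC40A1 (r = 0.406) to that of KRT6A.

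The subtype and keratin lists lay above their matched random lists. Median rho was 0.702 for Moffitt basal-like genes, 0.602 for Moffitt classical genes, 0.604 for Collisson classical genes and 0.702 for keratins, against 0.447, 0.417, 0.372 and 0.445 for random lists matched on expression (percentile 100 of 10000 lists each). Activated stroma genes had a median of 0.599 and smooth muscle genes one of 0.602. Ribosomal protein genes lay below, with a median of 0.243 against 0.426 (percentile 0), and reference genes too, with 0.242 against 0.373 (percentile 2.74). RPL31 (rho = −0.211, r = 0.0708), RPL37 (rho = −0.21, r = −0.0749), POLR2A (rho = −0.177, r = −0.132), SMARCA4 (rho = −0.0965, r = −0.0386) and RPS19 (rho = −0.0847, r = −0.0518) had the lowest values among list genes (adjusted permutation p for rho of 0.074, 0.077, 0.14, 0.43 and 0.49). For T and NK cell genes the median of 0.488 lay within the range of random lists (percentile 83.6). The random lists were matched on expression and not on spread across tumours. Median rho was 0.567 in the 3441 genes with the widest spread and 0.29 in the 3441 with the narrowest. Spread could therefore place a list above or below its random lists, and this was not tested. The draws also ignored correlation among the genes of a list, so the percentiles may be too extreme.

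**Figure D4:**
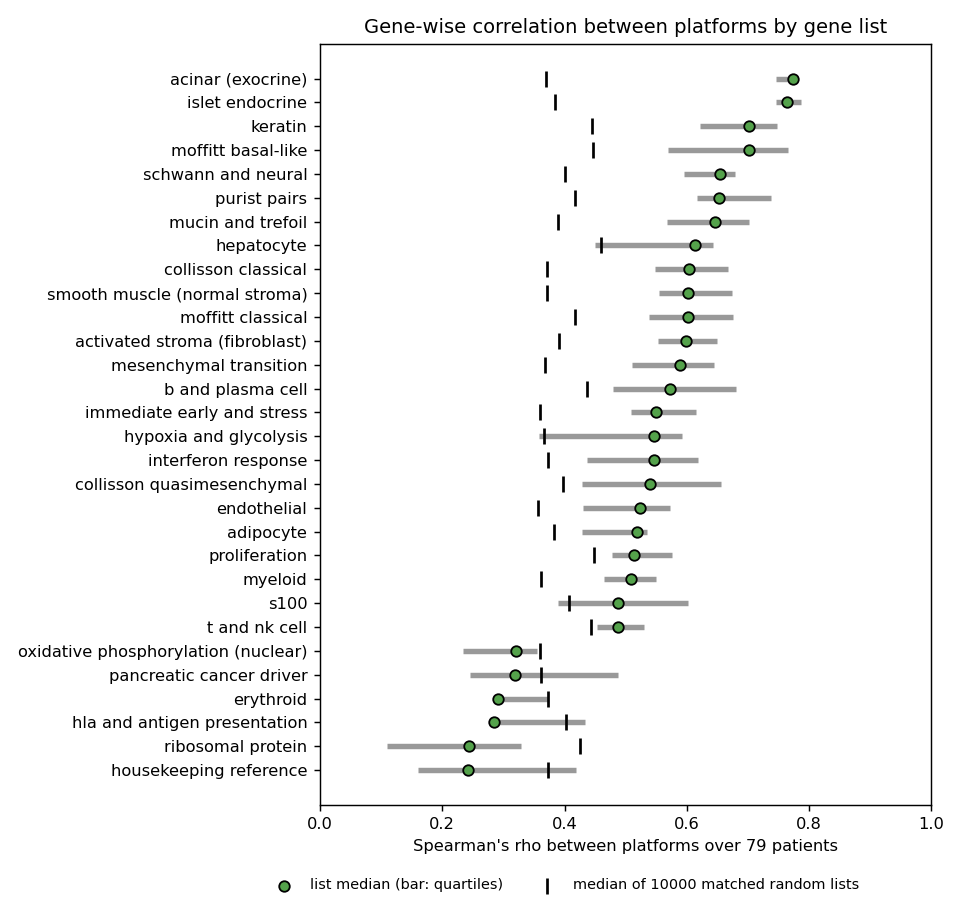
Median Spearman's rho between platforms over 79 patients (x axis) for the genes of each fixed list (y axis), with the quartiles of its genes as a bar and the median of 10000 random lists matched on expression as a tick. Acinar genes lie highest at 0.773 and reference genes lowest at 0.242.

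Detection and composition were compared last. At a threshold of 1 on the rescaled scale, 13369 ± 618 (SD, n = 79) of 16653 genes were detected on the whole transcriptome and 13156 ± 220 on exome capture (permutation p = 0.00085, higher on exome capture in 11 of 79 patients). At a threshold of 0.1 the order turned, with 14599 ± 748 and 14933 ± 148 genes (p = 1e-05, higher on exome capture in 69 patients). Ribosomal protein genes took 5.79% ± 1.17 of the shared-gene total on the whole transcriptome and 2.49% ± 0.425 on exome capture, and were higher on exome capture in 2 patients (p = 1e-05, the smallest that 100000 swaps can give). Of all whole-transcriptome TPM, small structured RNA took 60.7% ± 8.93, long noncoding RNA of the fixed list 0.72% ± 0.236 and replication-dependent histones 0.0971% ± 0.0339 (SD, n = 79). None of these 3 lists had a row shared with the exome capture table.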

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

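A median of 67.6% of the whole-transcriptome TPM lay in 6857 features with no row in the exome capture table, which the comparisons do not use. RN7SL2 and RN7SL1, the RNA of the signal recognition particle, took medians of 21.8% and 20.4%, RN7SK took 8.95% and SNORD3A took 5.90%. It is listed because the signal lies outside the main measurement, and its cause was not tested.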

How the results depend on the processing

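The alternatives without the 3 patients with many whole-transcriptome genes at 0, with oversized genes kept or left out by the ceiling alone, with deposited exome capture values in the score and with platform offsets removed were chosen after seeing the data. The level test on TPM as deposited was not run, since the tables share no unit. The cause of each change below was not tested, except where the setting itself gives it.

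Among paired results, dropping the patient block ended the call of the S100A2 to SLC40A1 ratio (0.5562, p = 0.11) and the list calls of acinar genes (−3.09) and keratins (0.641), and changed no other main call. It left 5348 genes called. Median centring gave 3049 genes higher and 2112 lower. Calls of basal-like tumours matched in 74.7% to 83.5% of patients over the other thresholds, weights recalled from the published classifier and platform medians, and in 92.4% after offset removal. Leaving out the 171 of 632 pair orders within 1.5-fold gave 75.9% matching over all pairs, against 67.9%, with 86.4% for PTGES and CLDN18 and 82.5% for KRT5 and CLRN3, both past the threshold no longer. The split at platform medians (1 and 4 pairs) gives no direction, since it removes any shift and ties alone make the basal-like groups unequal (39 and 27).

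Without the 3 patients, acinar genes (−3) and keratins (0.621) no longer passed. With oversized genes kept, 2 lists passed, and acinar genes (−2.68), ribosomal protein genes (−1.15), oxidative phosphorylation genes (−1.19) and keratins (0.651) did not. Keratins also failed with a minimum of 5 (0.641), median centring (1) and quantile normalization (0.716). Median rho was 0.341 with Pearson's r, 0.325 as deposited and 0.422 after quantile normalization. With Pearson's r, list medians moved for Moffitt basal-like (0.77), activated stroma (0.655), smooth muscle (0.695), T and NK cell (0.436), hepatocyte (0.811), proliferation (0.608), hypoxia (0.462), keratin (0.782), ribosomal protein (0.194) and oxidative phosphorylation genes (0.245). The difference in detected genes turned to 334.37 at a threshold of 0.1. The ribosomal protein share of whole-transcriptome TPM was 1.989% of all features (54 genes) and 5.79% of shared genes (49 genes), so total and members both differ. Of 1113 named-gene results, 1069 kept direction and call, 14 lost a call, 18 gained one, and 12 uncalled ones changed sign. The patient block, the filters and the handling of oversized genes leave a gene's difference unchanged by construction, and every change came from the other settings. In these, of 125 genes, 102 stayed the same with median centring, 115 with quantile normalization, 119 with a pseudocount of 0.1 and 120 without the 3 patients. Many of these genes had been named for large differences. The score difference was −0.097 (p = 0.37) with deposited exome capture values, which changes the log base, the rescaling and the genes (CTSE and CEACAM6 added). It was −0.805 (p = 1e-05) with these as log2 and 0.037 (p = 0.81) without the added genes. With ranks it is 0 by construction. Calls were gained by the proliferation list with quantile normalization and the mucin list with the ceiling alone. TPM keeps no depth, so no limit from depth could be set.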

Other observations

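The tests on tumour pieces, low expression, high expression and shared symbol entries were chosen only after the result was seen. Chance can be excluded for the gene count between platforms: of 100 splits with platform swapped within patients, only the real one (1) called as many as 5348 genes, and the highest other called 249.

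Basal-like orders were more frequent on exome capture. Reads shared among keratin 6 copies are argued against as the whole cause, because the difference was 1.15 ± 0.125 (SE) pairs over the 7 pairs without KRT6A. Different pieces of the tumour stay open. The 17 calls that differed all went one way (exact McNemar p = 1.5e-05), unlike pieces taken at random. A systematic choice of tissue could do the same. A choice of more basal-like pieces alone would raise every pair, and some pairs fell. The log2 ratio of PTGES to CLDN18 differed by −1.07 ± 0.164 (SE) and that of C16orf74 to DDC by −1.19 ± 0.148, while the ratios of the other pairs rose. Other choices of tissue stay open. The 21 acinar genes kept were all lower on exome capture, but 5 of the 26 had been left out as oversized. Smooth muscle genes moved both ways, with 4 rises and 6 falls in 17. Correcting each log ratio by the mean difference of the other patients raised matching orders from 67.9% to 87.0%, by 19.2 points, as would any shift that the patients share. Constant gene offsets and a systematic choice of tissue therefore cannot be told apart here, and no biological explanation was tested.

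Gene-wise correlation was weak for many genes. Low expression is argued against, since median rho was 0.383 in the 25% of genes with the highest level and 0.46 in the 25% with the lowest, a difference of −0.0769. A few poor whole-transcriptome libraries are argued against, since the median rho over all kept genes rose by 0.022 without the 3 patients. A narrow spread of a gene across tumours may contribute: median rho was 0.567 in the 25% with the widest spread and 0.29 in the 25% with the narrowest, a difference of 0.277. Spread holds noise as well as tumour differences, and this was not separated; no biological explanation was tested.

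Oversized exome capture values were found in 810 shared genes, 351 of them over the ceiling, with medians of 57.7 for DDX39B, 56.2 for TUBB and 51.8 for PRPF31, chosen after their values were seen. High expression is argued against as the whole cause for the genes over the ceiling. Of the 351 genes highest on the whole transcriptome, 5.7% were over the ceiling. This is a larger share than the 351 of all 17463 shared genes, so level may still contribute. The share among the highest genes was chosen as a measure after a ratio of median levels, 2.27 for the 351 genes and 0.968 for all 810, had not decided. Log values summed over annotation entries that share a symbol are a candidate explanation, since 69.8% of the oversized genes sat beside another one, against at most 13.6% in 1000 shuffles, with 121 on chromosome 6 and 136 on X. The entries could not be counted without the annotation used, and no biological explanation was tested.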
